A study of Mus musculus with 2 samples.

How the data were processed

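RNA of brown adipose tissue and of brown adipocytes differentiated in culture was extracted with Trizol, amplified and labelled with the Agilent low input linear amplification kit, and hybridised on 2 two-colour Agilent mouse arrays, per the labels' protocols. Each array set RNA of a mouse without PKGI (KO) against RNA of a wild type littermate (WT). KO was in Cy5 and WT in Cy3 on the tissue array, and the reverse on the adipocyte array. Further biological replicates were measured by quantitative PCR only, per the series' design text, and those values are not used here.

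Per the file headers, the deposited scanner files hold spot intensity values (mean signal and median local background of the green and red dye) from Agilent Feature Extraction 9.5.1.1 with the protocol GE2-v5_95_Feb07. The same deposited files give processed intensity, background-subtracted and dye-normalized by Feature Extraction, and the log10 ratio of red over green. The authors' deposited value table of the series also holds log10 ratios. Set against the scanner values it was Feature Extraction's ratio with KO over WT on both arrays, the sign being turned for the adipocyte array, within 0.02 on the log2 scale. It was empty for 7623 gene spots of the tissue array and 6968 of the adipocyte array, all with a log ratio of 0, and its medians on the log2 scale were 0.09 and 0.02. Its scale and direction are therefore known, and why those spots were emptied is not stated. A second deposited copy of each array held the same extraction, with signals equal in the tissue file and within 0.498% in the adipocyte file, and was used only for that check. The genome build of the probe coordinates is not given in the sources used here.

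Ratios were computed from the mean signals and local backgrounds with limma 3.58.1 in R 4.3.3. Of 45018 spots per array, 1639 were controls. Spots with an outlier flag of the spot or its background in either dye (1215 of the gene spots on the tissue array and 203 on the adipocyte array) were left out. Background was corrected with normexp (saddle method, offset 50), control spots included, and each array was normalized by loess with weight 0 for controls. Outlier spots were at first kept in the background fit and left out afterwards. On the tissue array that gave 35 genes at least 2-fold higher and 73 lower, and after those first values were seen the spots were left out before the fit. The set of flags, and counting only genes found in the reference table, were also settled after the files were seen. Saturated spots (4 on the tissue array, 0 on the other) were kept. Spots of a probe were averaged. A probe was kept when well above background in at least 1 channel, and a gene's value is the mean over its kept probes, with all log2 ratios given as KO over WT. Of the genes with several kept probes, 6494 on the tissue array and 6588 on the adipocyte array, the median SD between probes was 0.15 and 0.14. Among those at least 2-fold different, 2 of 105 and 1 of 316 had probes of both signs.

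Probes were named from the RefSeq gene table of GRCm38.p6 through their accession (22942 probes), symbol (6664) or a unique synonym (3108), giving 19502 genes, and 8458 probes matched no gene and are not reported. No coordinates of that table are used. A gene not well above background in a channel on all of its probes has only a bound, written "at least N-fold", taken between the bright channel and the higher of the dim value and the lowest signal among probes well above background, per channel after loess and Aquantile scaling. Such bounds, like all ratios given here, are open to dye bias of single genes, as no array was repeated with the dyes swapped.

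With 1 array per comparison there was no test, no paired analysis and no check between replicates. Genes were counted at a 2-fold difference. For each of 29 gene lists fixed before the data were examined, the median log2 ratio of the kept members was set against 10000 random lists of the same size matched on brightness in 20 bins, which describes that array only, and "inside the random range" means within 95% of the random lists. In the white fat list the old name of Slc7a10 also matched a synonym of Trip4, a gene unrelated to that list, which stayed in it. The genes named were fixed by a rule beforehand: all probes of Prkg1; per array the 8 highest and 8 lowest genes measured in both channels on all kept probes with the same sign; up to 3 genes each way by bound; up to 4 members past 2-fold of each list, or else the 2 largest; up to 8 genes past 2-fold on both arrays each way and 4 in opposite directions; and Ucp1, Ppargc1a, Pparg, Cebpa, Fabp4, Adipoq, Slc2a4, Insr, Irs1, Tfam and Cycs. Cidea, Acta1 and Tnnc2 on the tissue array, Cox6a2, Klf15, Lpin1, Eif2s3y, Kdm5d and Ddx3y on the adipocyte array, and Uty and Zfy1 were named after their values were seen. Not every gene picked by the rule is reported here.

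The steps were tested on simulated data built from the signals of each array. With 50 genes at each size among 20571 gene names of the tissue array, 14% of true 2-fold, 68% of 3-fold and 80% of 4-fold differences were counted as 2-fold, and 0 of 20371 unchanged genes were. With 19478 gene names of the adipocyte array the shares were 16%, 78% and 90%, and 0 of 19278 unchanged genes were counted. The offset shrinks the ratios of dim genes, so counts understate 2-fold differences, and the simulated noise is that of repeated spots and not of animals. In simulated lists of 30 genes, 5 of 100 without a shift, 82 of 100 with a log2 shift of 0.3 and 100 of 100 with 0.6 fell outside the random range. Alternatives fixed beforehand were no background subtraction, normexp with offset 0, Feature Extraction's own ratios, median centring without loess, probes well above background in both channels, no brightness filter, the brightest probe per gene, leaving out saturated spots, the second scanner copy and the deposited value table. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.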

Results

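Gene expression was compared between mice lacking PKGI (KO), the cGMP-dependent protein kinase encoded by Prkg1, and wild type mice (WT) of the C57BL/6N background. PKGI is activated by cGMP, the second messenger of nitric oxide and natriuretic peptides. The data are 2 two-colour microarrays. On the BAT array, brown adipose tissue (BAT, the heat-producing fat of mice) of a KO mouse was labelled with Cy5 and that of a WT littermate with Cy3. On the adipocyte array, brown adipocytes differentiated in culture from precursors of a KO and a WT littermate were compared with the dyes the other way round, KO in Cy3 and WT in Cy5. There was 1 array per comparison and no replicate array, so no test between genotypes was possible, no p-value is given, and values describe these RNA samples and not the genotypes in general. Neither comparison was repeated with the dyes swapped, so within an array dye bias of a single gene cannot be told apart from a difference between KO and WT. "Higher" and "lower" mean in KO relative to WT on that array, and genes are counted when the difference is at least 2-fold (a log2 ratio of 1 or more in size). Each array held 45018 spots, with 41174 different gene probes. On the BAT array 74.1% of the gene spots were well above background in the KO channel and 63.1% in the WT channel, and on the adipocyte array 68.1% and 70.1%. Probes spotted up to 10 times on an array differed with a pooled SD of 0.10 on the log2 scale on the BAT array (185 probes) and 0.09 on the adipocyte array (193 probes), which measures spotting and scanning only.

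Prkg1, the targeted gene, was examined first as a check of the labels. It has 4 probes on the array, all on chromosome 19 in the coordinates of the array files, whose genome build is not stated. Both probes well above background in each channel were lower in KO on both arrays. The probe at 30268225 to 30268284 had a log2 ratio of -1.29 on the BAT array and -0.94 on the adipocyte array, and the probe at 30264319 to 30264378 had -1.22 and -2.31. The probe at 30408200 to 30408259 was not well above background in the WT channel of either array (0.01 and 0.17), and the probe at 31441438 to 31441497 was not well above background in any channel. The gene mean over the 3 kept probes was -0.84 on the BAT array and -1.03 on the adipocyte array, and it was -0.073 on the BAT array when outlier spots stayed in the background fit (called "with outlier spots" below). Which part of Prkg1 was deleted is not given in the sources used here, so it is not known whether these probes lie inside it.

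The BAT array asks how brown fat of a mouse without PKGI differs from that of a WT littermate. Transcripts of skeletal muscle were far lower in KO. Of 33 skeletal muscle genes kept, 31 were at least 2-fold lower in KO and none was higher, with a median log2 ratio of -2.32 (-1.48 with outlier spots), below all of 10000 random lists matched on brightness. The slow troponin T gene Tnnt1 was 9.91-fold lower, the sarcomere crosslinker Actn2 9.63-fold, the myosin heavy chains Myh2 and Myh7 9.32-fold and 9.27-fold, and the mitochondrial creatine kinase Ckmt2 8.07-fold. The abundant muscle actin Acta1 had a log2 ratio of -2.33. Other genes among the lowest 8 measured in both channels were Atp1b4 (-3.28), Tceal7 (-3.26) and Ucp3 (-3.15). In the smooth muscle contractile list 4 of 20 genes were at least 2-fold lower and none higher (median -0.48, -0.30 without loess and -0.17 with outlier spots), namely Tpm2 (-2.02), Tpm1 (-1.83), Des (-1.45) and Synpo2 (-1.13), of which the tropomyosins and desmin are also made in skeletal muscle. Acta2 had -0.74, with its 5 probes between -1.50 and -0.17.

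Ucp1, the uncoupling protein through which brown fat makes heat, was 3.57-fold lower in KO tissue (log2 -1.84). Of 27 thermogenic and brown fat identity genes kept, 7 were at least 2-fold lower and 1 was higher, with a median of -0.35, below all random lists, that was -0.025 without loess and -0.10 with outlier spots. The lower genes included the fatty acid carrier Fabp3 (-2.83), the elongase Elovl3 (-2.14), the proton channel Otop1 (-1.38) and S100b (-1.29), while Cidea was higher (1.01). Fabp3 is also abundant in skeletal muscle, whose genes were lower on the same array. Ppargc1a, a coactivator that drives mitochondrial biogenesis, had -0.35. Genes of adipocyte differentiation and lipid storage lay around 0, with 2 of 31 at least 2-fold higher, none lower and a median of 0.00 (0.32 without loess). The 2 were the adipocyte protease Cfd (1.78) and the transcription factor Klf15 (1.02). Pparg, the main regulator of fat cell differentiation, had 0.82, the adipokine Adipoq 0.77, Cebpa 0.03, the fatty acid carrier Fabp4 0.00 with 3 probes between -0.67 and 0.35, and the insulin-regulated glucose transporter Slc2a4 -0.50.

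Lipid synthesis genes were lower in KO tissue. Of 28 fatty acid and triglyceride synthesis genes, 4 were at least 2-fold lower and 1 was higher, with a median of -0.60, below all random lists, that was -0.30 without loess and -0.17 with outlier spots. Fatty acid synthase Fasn was 4.22-fold lower, the desaturase Scd1 3.06-fold lower and the acyltransferase Agpat2 2.59-fold lower, whereas the phosphatidate phosphatase Lpin1 was 2.52-fold higher. Among 24 glycolysis genes 5 were at least 2-fold lower and 1 higher (median -0.49, -0.23 without loess and -0.22 with outlier spots), with the lactate carriers Slc16a3 (-1.22) and Slc16a1 (-1.12) and the phosphofructokinase Pfkl (-1.09) lower and the aldolase Aldoa (1.32) higher. The 25 TCA cycle genes had a median of -0.28 (-0.05 without loess, -0.47 with Feature Extraction's ratios) with none past 2-fold, the lowest being Ogdh (-0.88) and Pdhx (-0.84). The 29 fatty acid oxidation genes had a median of -0.30, which turned to 0.12 without loess, and 2 of them, Acsl5 (-1.19) and Acads (-1.07), were at least 2-fold lower. On the same array 31 of 33 skeletal muscle genes were at least 2-fold lower (median -2.32). The 77 respiratory chain and ATP synthase genes had a median of -0.05 (0.37 without loess), inside the range of random lists, but -0.22 with Feature Extraction's ratios and the deposited table and -0.18 with outlier spots, below that range, and only Cox6a2, the muscle form of a cytochrome oxidase subunit, passed 2-fold (-2.86). The 24 mitochondrial biogenesis regulators had a median of -0.06 (0.11 without loess) with none past 2-fold; Esrra had -0.41, Tfam -0.14 (0.11 without loess) and Cycs, the gene of cytochrome c, -0.52.

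The signalling lists held few differences in the tissue. Among 30 genes of the NO, natriuretic peptide and cGMP pathway, 1 was at least 2-fold higher and none lower (median 0.01). It was Rgs2, a regulator of G protein signalling, at 1.89 with probes at 1.29 and 2.49. The list includes the targeted gene Prkg1, which was under 2-fold as the mean of its kept probes (-0.84). It had -1.26 over the probes well above background in both channels. Of 38 insulin and IGF signalling genes none passed 2-fold (median 0.01); the largest values were Trib3 (0.96) and Igfbp2 (-0.94), with Insr at -0.07 (0.17 for its brightest probe) and Irs1 at -0.04. The 34 RhoA, ROCK and actin regulators had a median of -0.10 (0.01 without loess), inside the random range except for the brightest probe per gene (-0.12), with Arhgef12 at -0.58 and Arhgef1 at -0.54.

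Markers of other cell types were measured in the same tissue RNA. The 28 macrophage genes had a median of -0.05 with none past 2-fold (Trem2 0.48, Aif1 -0.45), and the median was 0.07 without loess. The 26 lymphocyte genes had 0.06 (-0.32 without loess), with Cd3g at -1.05 the 1 gene past 2-fold. The 25 endothelial genes had -0.22 (0.03 without loess, -0.09 with outlier spots) with Eng at -0.54 and Cldn5 at -0.45. The 10 erythroid genes had -0.21, inside the random range, but below it with offset 0 (-0.34), with Feature Extraction's ratios and the deposited table (-0.42), without loess (-0.56) and with outlier spots (-0.03), and the transferrin receptor Tfrc had -1.94. The 17 nerve and Schwann cell genes had 0.05 (-0.12 without loess), with S100b the 1 gene past 2-fold. The 47 preadipocyte and extracellular matrix genes had -0.08 (0.03 without loess, -0.14 for the brightest probe per gene), with Spp1 at 1.17 and Ccn2 at -1.03.

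Sex-linked transcripts differed between the tissue samples. The Y-linked genes Eif2s3y, Kdm5d and Uty were not well above background in KO and at least 84.7-fold, 4.44-fold and 2.48-fold lower, and Ddx3y was lower on both its probes, at -4.48 on the probe well above background in both channels and -2.64 on the other, not well above background in KO, whereas the fifth, Zfy1, was not well above background in WT (-0.05). Xist, the RNA of the inactive X chromosome of females, was higher in KO on its 3 probes (1.63 to 7.72), with a mean of 5.80 over the 2 well above background in both channels and the third not well above background in WT, and its antisense partner Tsix was at least 4.42-fold higher. Probes of Xist and Tsix come from overlapping genes, and whether each reads a single strand was not checked.

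Across the BAT array 15615 genes were kept, of which 125 (0.801%) were at least 2-fold higher and 381 (2.44%) at least 2-fold lower in KO. Of the genes past 2-fold 24.7% were higher, against 59.6% with the log ratios of Feature Extraction, which counted 1402 higher and 950 lower. With outlier spots 35 genes were higher and 73 lower, and centred on spiked-in controls 17 were higher and 4575 lower. The highest genes measured in both channels were Trp53inp1 (5.64-fold), then, as log2 ratios, Skor1 (2.41), Ugt2b34 (2.26), Col27a1 (2.19), Olfr821 (2.14), Vsig8 (2.02), Inmt (2.01) and the ribosomal protein gene Rplp2 (1.89). Where a channel was not well above background, Pramel48 was at least 3.60-fold and Ankk1 at least 3.48-fold higher, and Areg, a growth factor of the EGF family, at least 3.07-fold lower. By the fit of Feature Extraction, spiked-in control transcripts read 0.84 too high in KO over WT on this array and 0.22 too high on the adipocyte array. Ratios here are relative to the middle of all genes. Counts given as centred on spiked-in controls subtract those fitted shifts from every ratio. The controls' own ratios after the background and loess steps used here were not computed, so such counts only show the effect of a shift of that size.

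**Figure D1:**
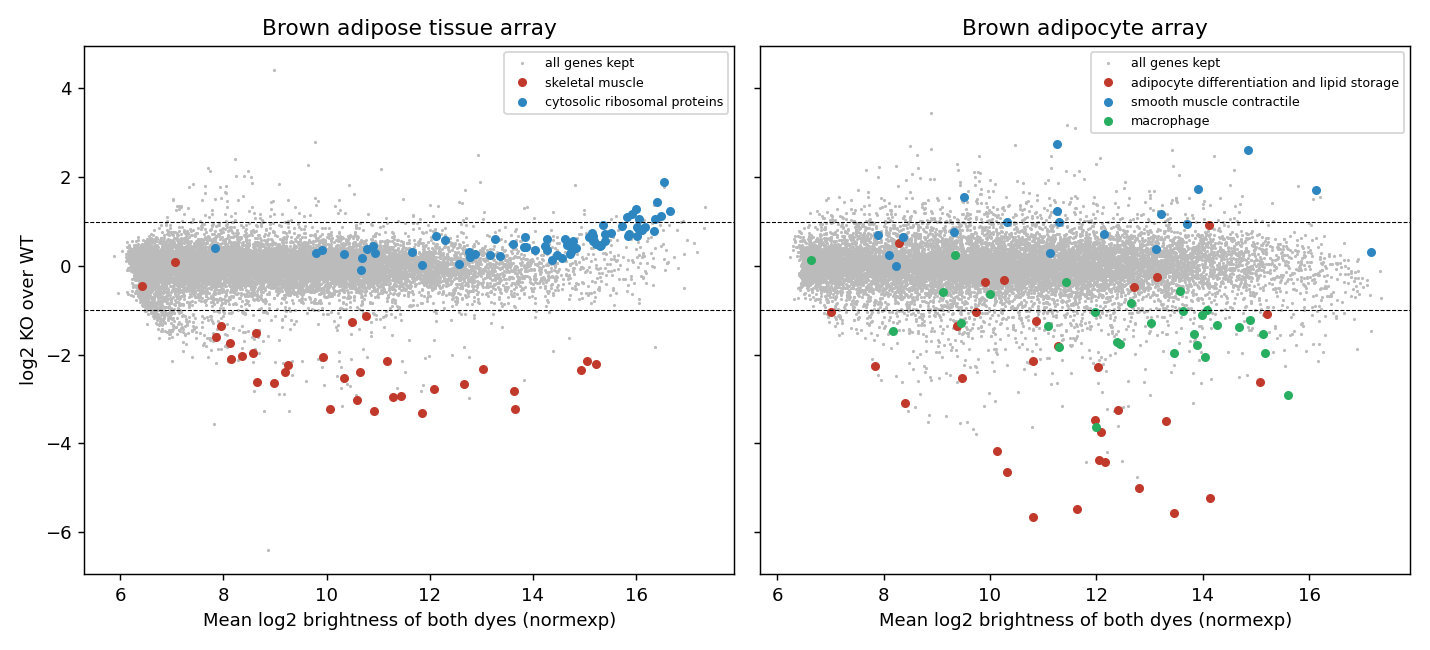
Log2 KO over WT of each gene against its mean log2 brightness on the BAT array (left) and the adipocyte array (right), 1 array each, with coloured points for the genes of named lists and dashed lines at 2-fold. On the left 31 of 33 skeletal muscle genes lie below the lower line, and on the right 25 of 31 adipocyte genes and 21 of 29 macrophage genes do.

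The adipocyte array asks how fat cells formed in culture from KO precursors differ from those of WT precursors. Genes of mature fat cells were far lower in KO. Of 31 adipocyte differentiation and lipid storage genes, 25 were at least 2-fold lower and none was higher, with a median of -2.52, below all random lists. Cfd was 50.8-fold lower, Fabp4 47.7-fold, the lipid droplet protein gene Cidec 44.5-fold, Adipoq 37.2-fold and the carbonic anhydrase Car3 32.2-fold lower. The retinol carrier Rbp4 (-4.76), the lipid droplet coat gene Plin4 (-4.65) and the melanocortin receptor accessory gene Mrap (-4.41) were also among the lowest 8 measured in both channels. The transcription factor genes Pparg and Cebpa were 11.2-fold and 4.44-fold lower, and Slc2a4 was 11.1-fold lower.

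Brown fat genes were lower in the KO culture too. Ucp1 was 13.8-fold lower, Cidea 10.4-fold, Plin5 6.00-fold and Ppargc1a 4.95-fold lower, and Otop1 was at least 5.52-fold lower. Of 28 thermogenic genes kept, 12 were at least 2-fold lower and none higher (median -0.68, below all random lists, -0.33 with both channels above background and -1.12 with offset 0). Among the 25 mitochondrial biogenesis regulators 2 were at least 2-fold lower (median -0.24), Ppargc1a and Ppargc1b (-2.61), while Tfam had 0.16 with probes between -0.13 and 0.45. All 25 TCA cycle and pyruvate dehydrogenase genes were below 0 and 7 of them at least 2-fold lower (median -0.75), with pyruvate carboxylase Pcx 8.88-fold and the isocitrate dehydrogenase subunit Idh3a 5.67-fold lower. Of 78 respiratory chain and ATP synthase genes, 8 were at least 2-fold lower and 1 higher (median -0.35); Cyc1 had -1.49, Cox6a1 -1.48, Atp5b -1.47 and Cycs -0.72, and Cox6a2 was the higher gene (2.14-fold).

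Lipid metabolism genes followed the same direction. Of 28 fatty acid and triglyceride synthesis genes 15 were at least 2-fold lower and none higher (median -1.08), among them Thrsp (-3.60), Pnpla3 (-3.52), the glucose-responsive transcription factor Mlxipl (-3.16) and Scd1 (-3.08). Of 29 fatty acid oxidation genes 8 were at least 2-fold lower and 1 higher (median -0.74), with the acyl-CoA synthetase Acsl1 at -3.74, Acaa2 at -1.90, Hadh at -1.69 and Acadvl at -1.44. Of 24 glycolysis genes 4 were at least 2-fold lower (median -0.47), namely Aldoa (-1.88), Ldhb (-1.54), Pfkfb3 (-1.52, with 1 of 3 probes not well above background in KO) and Pgam1 (-1.12).

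Contractile and matrix genes were higher in the KO culture. Of 19 smooth muscle contractile genes 7 were at least 2-fold higher and none lower, with a median of 0.95, above all random lists. The calponin Cnn1 was 6.73-fold, Tagln 6.14-fold, Tpm2 3.31-fold and the myosin light chain Myl9 3.25-fold higher. Of 47 preadipocyte and extracellular matrix genes 10 were at least 2-fold higher and 1 lower (median 0.25). Ccn2, a matrix-associated growth factor, was 10.3-fold higher, the collagen Col8a1 8.96-fold, Ccn5 6.07-fold and the calcification inhibitor Mgp 3.54-fold higher. The 33 RhoA, ROCK and actin regulators had a median of 0.12, inside the random range except without loess (0.11), with Rnd3 at 0.83 and Mylk at 0.77 (1.16 without a probe not well above background in KO) and none past 2-fold. The 30 skeletal muscle genes had a median of 0.00 (0.12 without loess) with 2 at least 2-fold higher, Acta1 (1.52) and Myf5, which was at least 2.08-fold higher.

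Macrophage markers were lower in KO alongside the adipocyte genes. Of 29 macrophage genes 21 were at least 2-fold lower and none higher (median -1.34, below all random lists), with the fungal receptor Clec7a 12.4-fold, the protease Ctss 7.56-fold, the lysozyme Lyz2 4.16-fold and the Fc receptor Fcgr1 3.92-fold lower. Of 18 lymphocyte genes 3 were at least 2-fold lower (median -0.36, -0.09 without loess and -0.14 without a brightness filter), Cd52 (-1.48), Cd28 (-1.45) and Rac2 (-1.27). Endothelial genes had a median of 0.02 (0.17 without loess) with 2 of 19 higher, Ecscr (1.43) and Flt1 (1.35). The 6 erythroid genes had a median of -0.04 (0.36 without loess), with Tfrc at -1.14. The 20 nerve and Schwann cell genes had -0.20 (0.03 without loess), with Uchl1 at 1.26 and Erbb3 at -1.19.

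In the NO, natriuretic peptide and cGMP list 2 of 29 genes were at least 2-fold higher and 4 lower (median 0.06, inside the random range). The list includes the targeted gene Prkg1, which counts among the 4 lower genes (-1.03). The soluble guanylate cyclase subunit Gucy1b1 was higher (1.36), Prkg2, the gene of the related kinase PKGII, was at least 2.09-fold higher, and Rgs2 (-1.59) and the phosphodiesterase Pde3b (-1.36) were lower. Of 39 insulin and IGF signalling genes 4 were at least 2-fold lower and 1 higher (median -0.20), including Slc2a4, Igfbp5 (-1.21, its probe well above background in both channels at -2.25) and, as the higher gene, Igfbp2 (1.75). Insr had -0.29 with probes at -0.66 and 0.08, and Irs1 had -0.08, or 0.16 with the log ratios of Feature Extraction. Xist was 10.3-fold lower in the KO culture, with 4 probes between -5.26 and -1.53, while the Y-linked genes Eif2s3y (-0.12), Kdm5d (0.07) and Ddx3y (0.61) were within 2-fold.

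On the adipocyte array 15112 genes were kept, of which 377 (2.49%) were at least 2-fold higher and 631 (4.18%) at least 2-fold lower in KO. Of the genes past 2-fold 37.4% were higher, against 47.8% with the log ratios of Feature Extraction, which counted 876 higher and 955 lower. Offset 0 gave 617 higher, and spiked-in controls 205 higher and 974 lower. The highest genes measured in both channels were Asb5 (3.44), Ccn2 (3.36), Col8a1 (3.16), the glutamate transporter Slc1a6 (3.10), Cnn1 (2.75), the tendon gene Tnmd (2.72), C1qtnf3 (2.70) and the glycine receptor subunit Glrb (2.64). Where a channel was not well above background, Msln was at least 2.91-fold, Hoxa11 at least 2.59-fold and Cpxm2 at least 2.51-fold higher, and the water and glycerol channel Aqp7 at least 8.48-fold and leptin, Lep, at least 5.90-fold lower.

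**Figure D2:**
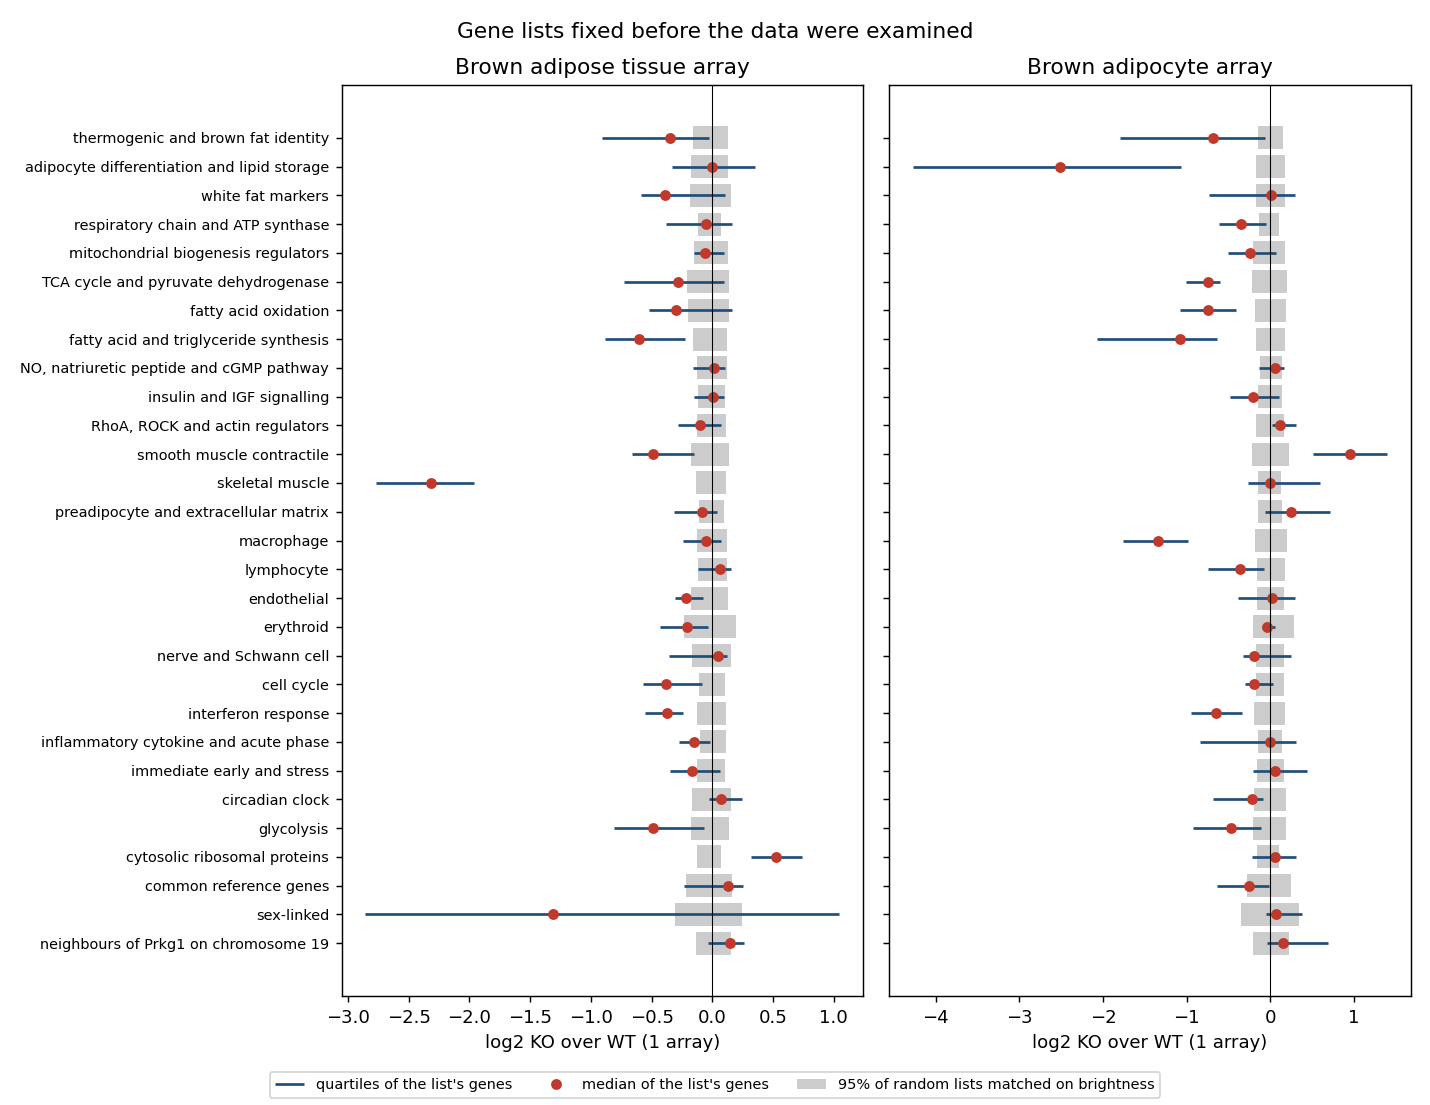
Median log2 KO over WT (points) and quartiles (lines) of the genes of 29 lists on the BAT array (left) and the adipocyte array (right), with grey bars for the range of 95% of random lists matched on brightness. Skeletal muscle genes (-2.32) lie farthest from 0 on the left and adipocyte genes (-2.52) on the right, and the smooth muscle list lies below its grey bar on the left (-0.48) and above it on the right (0.95).

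The arrays were then set against each other, to ask whether tissue and cultured cells differ from their WT partners in the same genes. Across 14272 genes kept on both arrays, which are not independent replicates, the ratios showed no correlation (Pearson r = 0.0012, Spearman rho = 0.0035), and r was -0.21 without loess. No gene was at least 2-fold higher on both arrays, where independent lists would share 2.55 (14 against 9.98 with offset 0, 77 against 48.8 with Feature Extraction's ratios and 77 against 48.5 in the deposited table), and 33 were lower on both, where independent lists would share 11.4 (67 against 27.9 with offset 0, 94 against 36.6 with Feature Extraction's ratios, 28 against 17.7 without loess, 15 against 2.91 with outlier spots and 401 against 267 on spiked-in controls). The lower genes included Ucp1, Fasn and Scd1, as well as Nat8l (-2.01 in tissue and -3.66 in cells), which makes N-acetylaspartate, G0s2 (-2.14 and -2.10), an inhibitor of the lipase Pnpla2, Clstn3 (-2.06 and -2.05), Fndc5 (-2.70 and -1.95), which is also expressed in muscle, and the acute phase gene Orm1 (-1.45 and -3.18). Opposite differences past 2-fold were seen for 16 genes higher in tissue and lower in cells (4.62 for independent lists) and 18 lower in tissue and higher in cells (6.28). These counts became 67 and 93 with Feature Extraction's ratios, 22 and 63 with offset 0, 37 and 38 without loess, 10 and 5 with outlier spots and 3 and 97 on spiked-in controls. Because the dyes are reversed between the arrays, a dye bias of single genes would also give opposite ratios. Such a bias would push r down too, so the value of r does not by itself show that the arrays share no differences. The counts for independent lists are not matched on brightness, and the opposite overlaps exceeded theirs as well. The excess of genes lower on both arrays therefore does not by itself show a shared direction.

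**Figure D3:**
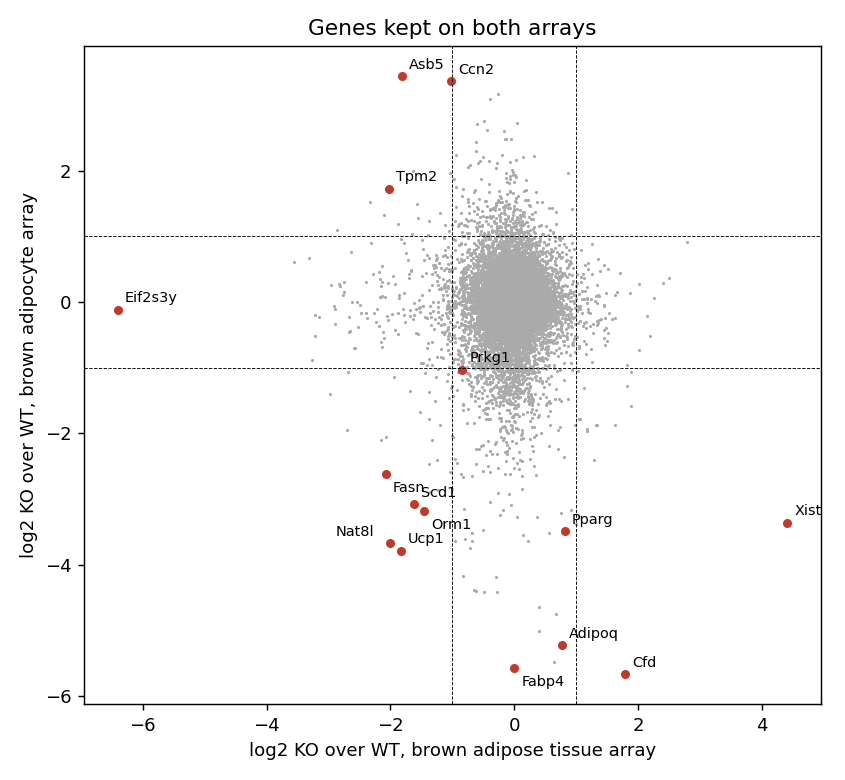
Log2 KO over WT on the BAT array (horizontal) against the adipocyte array (vertical) for the 14272 genes kept on both, with named genes in red and dashed lines at 2-fold. Ucp1, Fasn, Scd1, Nat8l and Orm1 lie at the lower left, Xist and Cfd at the lower right and Asb5, Tpm2 and Ccn2 at the upper left.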

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

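The tests of dye bias and of the share of adipocytes below were chosen after the values were seen, and the tests of muscle tissue, of normalization and of X-linked genes were written before theirs were. The normalization test also covers outlier spots kept in the fit, the order of the first run, whose values were seen before the processing was changed.

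Several results went opposite ways on the tissue and the adipocyte array. The differences were not tested, as each rests on 1 array, and values are tissue minus cells on the log2 scale. KO had the other dye on each array, so a gene with opposite ratios here leaned to the same dye on both. Dye bias of single genes would give this as well and cannot be told apart here from a difference between tissue and cells. The smooth muscle contractile list was below the random range in tissue and above it in cells, a difference of -1.44 between the medians. Named genes past 2-fold both ways and lower in tissue were Asb5 (-5.26), Ccn2 (-4.39), Cox6a2 (-3.96), Acta1 (-3.85) and Tpm2 (-3.75). Those higher in tissue and lower in cells were Xist (7.77), Cfd (7.45), Cidea (4.39), Rgs2 (3.48), Lpin1 (3.21), Aldoa (3.20), Rplp2 (2.96) and Klf15 (2.07).

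Skeletal muscle genes were lower in KO tissue, with a median of -2.32 over 33 genes. Normalization as the whole cause is argued against by the list's highest median over all alternatives, -1.48. That value is from keeping outlier spots in the fit, which was not among the alternatives fixed beforehand. Over those the highest median was -2.07, without loess. Muscle tissue carried over into the WT sample may be the source. A second list of 35 muscle genes, such as Trdn, Myot and Cacna1s, written without knowledge of their values, had a median of -1.85 with 27 at least 2-fold lower. That list would also be lower if muscle-type expression differed between the genotypes, so it cannot tell these explanations apart. Transcripts known to be abundant in muscle took part, Acta1 at -2.33 and Tnnc2 at -2.21. Fabp3 of the brown fat list and Cox6a2 of the respiratory chain list are also muscle genes. A difference of muscle-type expression between the genotypes stays open and untested, as each genotype is a single animal.

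Y-linked genes were lower and Xist higher in KO tissue. For the Y-linked genes dye bias of single genes is argued against, since the median red over green log2 ratio of 5 of them was -2.15 on the tissue array (the bound of Kdm5d) and -0.20 on the adipocyte array, but Xist was higher in red on both arrays (4.41 and 3.36 over all kept probes), so gene-specific dye bias stays open for Xist. A WT sample from a male and a KO sample from a female may explain it: 5 X-linked genes known to escape inactivation (Kdm6a, Ddx3x, Kdm5c, Pbdc1 and Eif2s3x) had a median of 0.34, above the random range that ended at 0.30, although Eif2s3x had -0.32. Sex and genotype would then differ together on this array, and a mislabelled sample was not tested. Without chromosomes X and Y, 120 genes were at least 2-fold higher and 357 lower. Leaving these chromosomes out does not remove differences between the sexes in genes of other chromosomes, so these counts do not measure the share of sex.

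Adipocyte genes were lower in the KO culture, with a median of -2.52 over 31 genes. A smaller share of adipocytes as the only change among the cells is argued against, because smooth muscle genes were higher and macrophage genes lower, with 1.499 between their quartile ranges. A smaller share of adipocytes together with fewer macrophages would give the same gap, so it stays open. Gene-specific dye bias is argued against by the tissue array, where KO had the other dye and the third quartile of the list was 0.35, where dye bias needs the list median of -2.52 with its sign turned. Weaker differentiation of KO precursors may account for the adipocyte genes, and fewer macrophages for theirs, but neither was tested beyond this, and both cultures could also differ by chance between animals.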

How the results depend on the processing

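Keeping outlier spots in the background fit, centring on spiked-in controls and leaving out chromosomes X and Y or muscle genes were chosen after seeing the data. Centring on spiked-in controls subtracts the shift fitted by Feature Extraction, not one measured on the controls after loess. The second scanner copy was not run, as it holds the same extraction, and leaving out saturated spots moved no count. No paired analysis was possible because each comparison is 1 array. The cause was not tested unless given.

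Prkg1 was below 0 under every setting. On the tissue array (-0.84) it was -0.95 without background subtraction, -1.28 with offset 0, -1.12 with Feature Extraction's ratios and with the deposited table, -1.20 without loess, -1.26 with both channels above background, -0.64 without a brightness filter, -1.29 for the brightest probe, -0.073 with outlier spots in the fit and -1.68 on spiked-in controls. On the adipocyte array (-1.03) it was -1.26 with offset 0, -1.19 with Feature Extraction's ratios and the deposited table, -0.82 without loess, -1.63 with both channels above background, -0.79 without a filter, -2.31 for the brightest probe and -1.25 on spiked-in controls.

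On the tissue array 125 genes were at least 2-fold higher and 381 lower. The counts were 385 and 835 with offset 0, where dim ratios are not shrunk, 1402 and 950 with Feature Extraction's ratios, 1398 and 949 in the deposited table, 253 and 672 without loess, 35 and 73 with outlier spots in the fit, and 17 and 4575 on spiked-in controls, which shift every ratio. Of the 125 and 381 genes, 114 and 379 were among those of Feature Extraction. Leaving out both muscle lists left 125 and 323. This drops only the members of those lists. Other genes also made in muscle, such as Tpm2, Des, Fabp3 and Cox6a2, stay counted, so 323 is not a count free of muscle. On the adipocyte array (377 and 631) offset 0 gave 617 higher, Feature Extraction 876 and 955, the deposited values 874 and 953, and spiked-in controls 205 and 974. On spiked-in controls 0.37% of the tissue genes past 2-fold and 17.4% of the adipocyte genes were higher.

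Between the arrays r (0.0012) was 0.018 with Feature Extraction's ratios and the deposited table, -0.21 without loess and 0.030 with outlier spots in the fit. Genes past 2-fold the same way on both (33) numbered 81 with offset 0, 171 with Feature Extraction, of which 77 were higher, 170 in the deposited table, 15 with outlier spots in the fit and 401 on spiked-in controls.

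List medians and named genes were not recomputed on spiked-in controls, without chromosomes X and Y or without muscle genes. Of 32 list medians outside the random range, 29 to 32 stayed outside on the same side under each of the other settings and none moved to the other side (31 were measured with both channels above background, and 29 stayed). Of 26 inside it 22 to 26 stayed inside. Without loess 13 of those 26 turned sign, and 4 of the 32: fatty acid oxidation (0.12), endothelial (0.033) and immediate early genes (0.0042) in tissue and nerve genes in cells (0.029). Of 168 values of named genes past 2-fold, 160 to 168 stayed so under the planned settings (154 of 154 with both channels above background), 137 with outlier spots in the fit, and none turned sign. With outlier spots in the fit all losses were on the tissue array. There 35 of the 125 higher and 72 of the 381 lower genes stayed past 2-fold, while all 377 and 631 of the adipocyte array did. Signal over background limits the dim genes.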

Other observations

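Interferon response genes were below 0 on both arrays. In tissue 31 of 32 genes had a ratio below 0, with none past 2-fold and a median of -0.37 (-0.07 when outlier spots stayed in the background fit), below all random lists; the antiviral genes Ifit1 and Isg15 both had -0.84. In cells 32 of 34 were below 0 and 5 at least 2-fold lower (median -0.65), among them Rsad2 (-1.68), Mx1 (-1.51), Oas2 (-1.32) and Oasl1 (-1.21), in a culture where 21 of 29 macrophage genes were at least 2-fold lower as well (median -1.34). Cytosolic ribosomal protein genes were higher in KO tissue, with 67 of 68 above 0, 9 at least 2-fold higher and a median of 0.53 (0.95 without loess), above all random lists. Rplp2 (1.89), Rplp1 (1.45), Rpl5 (1.28) and Rps23 (1.24) led the list, and their probes are among the brightest of the array. In cells the same list had a median of 0.06 (-0.12 without loess), inside the random range, and Rplp2 at -1.07 was the 1 gene past 2-fold. Cell cycle genes had a median of -0.38 in tissue (-0.07 with outlier spots in the fit), with 32 of 40 below 0 and none past 2-fold (Tk1 -0.77, Birc5 -0.74), and -0.20 in cells (-0.32 without loess, -0.10 with Feature Extraction's ratios), where Ccnd1 was higher (1.25) and Cdkn1a lower (-1.02).

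Of 34 inflammatory and acute phase genes in tissue 4 were at least 2-fold lower (median -0.15, -0.45 without loess, -0.27 with Feature Extraction's ratios and -0.011 with outlier spots in the fit), Orm1 (-1.45), Orm2 (-1.36), Hp (-1.25) and Cxcl2 (-1.07), and in cells 7 of 37 were higher and 9 lower (median 0.00, -0.11 without loess), with Cxcl14 at 1.93, Orm2 at -2.90 and Hp at -2.40. White fat markers had a median of -0.39 in tissue, below the random range (-0.17 without a brightness filter, -0.04 with outlier spots in the fit), with none past 2-fold (Psat1 -0.78, Slc7a10 -0.70), and 0.01 in cells, where Sncg (-3.63), Retn (-3.04) and Lep, at least 5.90-fold lower, were among 5 lower genes and Hoxc9 (1.88) was higher. Immediate early and stress genes had -0.17 in tissue (0.004 without loess, -0.017 with outlier spots in the fit), with the metallothionein Mt2 at 1.71, and 0.06 in cells (-0.01 without loess), with Ccn1 at 1.42 and Atf3 at -1.18. Circadian clock genes had 0.07 in tissue, or 0.29 with Feature Extraction's ratios and the deposited table, above the random range (Bhlhe40 -0.85, Hlf 0.71) and -0.21 in cells (-0.37 for the brightest probe per gene; Hlf -1.95). Common reference genes had 0.13 in tissue (0.25 without loess, 0.03 without a brightness filter and with outlier spots in the fit), with Polr2a at 1.02 and Tfrc at -1.94, and -0.25 in cells (-0.48 without loess and -0.36 for the brightest probe per gene, below the random range), with Tfrc at -1.14. The neighbours of Prkg1 on chromosome 19 had 0.15 on both arrays, inside the random range, although the tissue value was at percentile 97.3 and above that range under 5 of the other settings, among them no loess (0.18) and offset 0 (0.22), with Lipa (-0.74) and Acta2 (-0.74) in tissue and Ch25h (2.48), Acta2 (1.24, with 1 of 5 probes not well above background in WT) and Fas (1.05) higher in cells. The sex-linked list, which holds Xist beside Y-linked genes that went the other way, had a median of -1.31 over 7 genes in tissue (-0.19 without a brightness filter, -0.07 with outlier spots in the fit, -3.03 with offset 0, -4.75 with Feature Extraction's ratios and the deposited table) and 0.07 over 7 genes in cells (0.21 without loess).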
